A study of Mus musculus with 24 samples.

How the data were processed

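The deposited table held RMA log2 values of 22690 probe sets on 24 arrays, made by the authors with RMA in R 2.15.0 according to the submitters' processing notes. Labels give total RNA extracted with TRIzol, biotin labelling and 1 array per mouse. Values ran from 2.03 to 14.1 with 0 missing, and array medians from 5.41 to 5.51, so no further normalisation was applied. The hybridisation dates, litters and animal pairs are not given in the sources used here, and 0 per-sample columns of the labels were left unused.

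Probe sets were matched to genes with the platform annotation supplied with the series. After 64 control probe sets were left out, 20380 had 1 gene symbol, 691 had several and 1555 were not listed. Of the 20380, 20351 were matched by gene ID to the GRCm38.p6 gene table and 0 changed symbol. Each of 12393 genes was represented by the probe set with the highest mean over the 24 arrays, chosen before any test, and 9167 genes whose probe set lay above the 40th percentile of its array on at least 2 arrays were tested.

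limma 3.58.1 in R 4.3.3 fitted 12 group means to all 24 arrays with 12 residual degrees of freedom. Moderated tests were made for 19 comparisons: 9 of a ligand with corn oil, 3 of genotypes on corn oil and 7 of ligand effects between genotypes. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with an adjusted p under 0.05 were called changed. The groups, the tests, the gene lists and the alternatives were fixed before the data were examined, and the settings without 2 arrays and, for lists, without single arrays were added after. Differences of effects are the change in the first genotype minus that in the second.

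Gene lists were tested with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Of 33 lists fixed in advance, 27 had at least 5 measured members and were tested. The report gives lists of drug-metabolising P450s, conjugation enzymes, transporters, S phase and mitosis, early growth genes, fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acids, gluconeogenesis, acute phase, interferon, endoplasmic reticulum stress, sex-biased genes, Nr1i3 neighbours and markers of hepatocytes, Kupffer, endothelial and stellate cells and neutrophils. Nr1i3, Cyp2b10, Cyp3a11, Cyp2c55, Cyp1a2, Cyp7a1, Pck1 and Gadd45b were named in every comparison whatever their p. Besides them the 12 largest rises and 8 largest falls of 4 main comparisons, the 5 largest of each in the others and up to 4 members of each list were covered by the rule, of which the report names only passing ones, and not all of these. Of 95 other probe sets of passing named genes, 2 had the opposite sign.

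The steps were tested on simulated arrays with 200 changed genes in each of 20 runs. In the comparison of TCPOBOP with corn oil in wild type 92.6% of genes changed 2-fold and 99.4% of those changed 4-fold were recovered, and 4.41% of calls were false. For the difference between wild type and knockout 73.5% and 97.9% were recovered, and 4.91% of calls were false. All 20 shifted lists and 0 of 20 unshifted ones passed the list test, but lists of correlated genes were not simulated. No 2 arrays were copies: over 276 pairs the largest share of equal values was 0.0485%, and the smallest SD of a difference was 0.171. Other settings tried were cyclic loess, other dim filters, the mean of probe sets, a variance trend with a robust prior, array weights, the replicate number as a block, a 2-fold limit, fewer arrays in the fit and leaving out each array. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.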

Results

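Gene expression was measured in livers of 24 mice of mixed C57BL/6x129Sv background, labelled female, with 1 Affymetrix array per mouse. The mice belonged to 3 genotypes. Wild-type mice carried mouse CAR, the constitutive androstane receptor encoded by Nr1i3, a nuclear receptor that controls drug-metabolising genes in the liver. Knockout mice lacked mouse CAR, and human CAR mice carried a human CAR transgene driven by the mouse albumin promoter on the knockout background. Each genotype received 4 treatments by intraperitoneal injection over 3 days: corn oil, phenobarbital at 100 mg/kg per day, CITCO at 30 mg/kg per day, or TCPOBOP at 3 mg/kg in 1 injection on the first day followed by corn oil. Livers were taken 6 h after the last dose. Per the labels, phenobarbital is an anticonvulsant that moves both receptors into the nucleus, TCPOBOP a ligand of mouse CAR and CITCO one of human CAR. Each of the 12 groups held 2 mice, and that number limits the precision of every value. Comparisons were of ligands with corn oil within a genotype, of genotypes on corn oil, and of ligand effects between genotypes. Values are log2 expression, changes are log2 fold changes with the standard error (SE) of the limma fit, and adjusted p-values are Benjamini-Hochberg values over 9167 genes. Counts given as within the list are adjusted over that list alone, and p-values of camera, a list test, over all lists.

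The Nr1i3 transcript, read by 1 probe set, lay between 6.84 and 8.0 on the 8 wild-type arrays and between 5.03 and 5.60 on the 16 arrays of knockout and human CAR mice. On corn oil its mean was 7.47 ± 0.15 in wild type, 5.11 ± 0.07 in knockout and 5.21 ± 0.24 in human CAR mice (SD, n = 2 each). Its log2 difference from wild type was -2.37 (SE 0.19, adjusted p = 3.91e-06) in knockout and -2.26 (SE 0.19, adjusted p = 1.55e-05) in human CAR mice. No ligand moved it past the threshold: its changes in the 9 ligand comparisons ran from -0.54 to 0.48, with a smallest adjusted p of 0.115. Where this probe set lies relative to the deleted part of the gene is not given, and the human CAR transcript was not analysed.

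**Figure D1:**
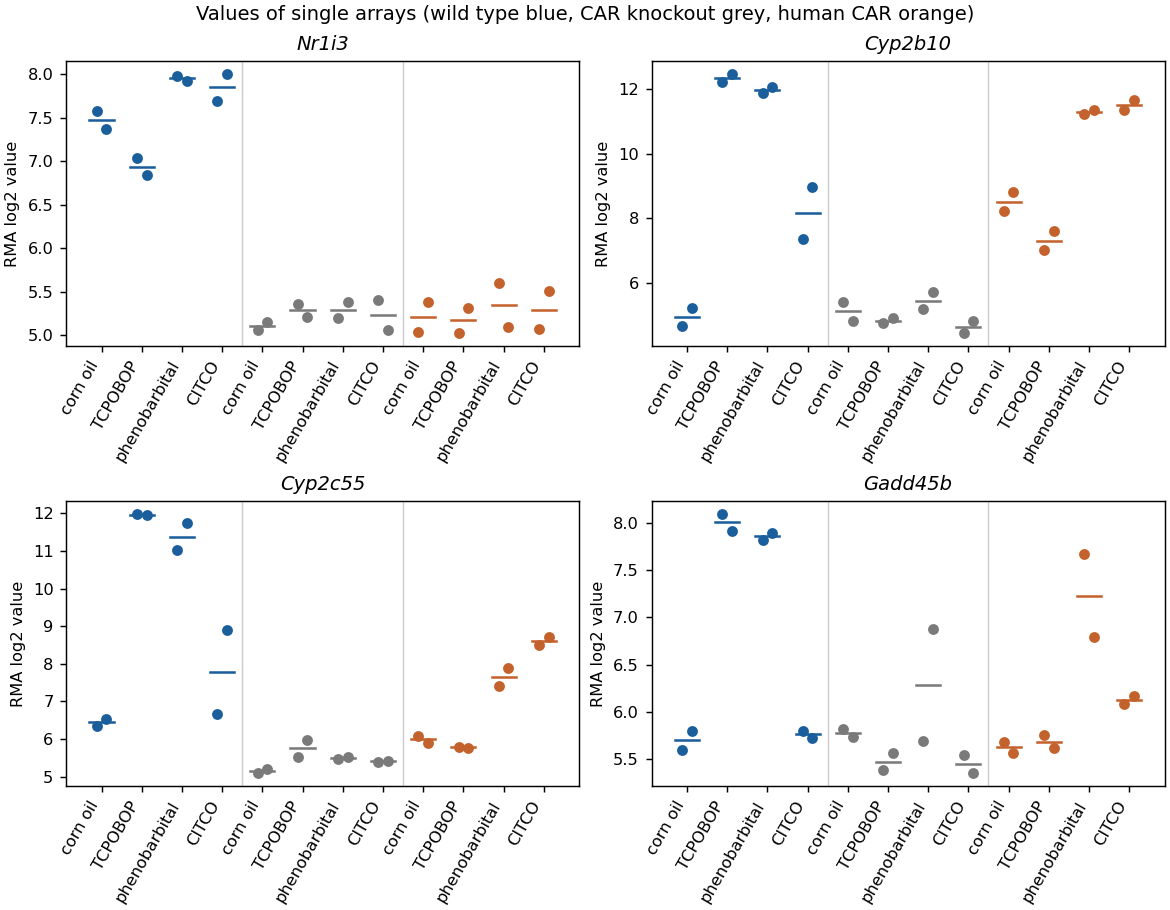
RMA log2 values of Nr1i3, Cyp2b10, Cyp2c55 and Gadd45b on each of the 24 arrays, where points are single mice and lines are means of the 2 mice of a group. Nr1i3 lay at or above 6.84 on every wild-type array and at or below 5.60 on every other array.

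2 arrays lay apart from the other 22. They were the knockout phenobarbital array of replicate 2 and the human CAR phenobarbital array of replicate 1, whose median correlations with the other arrays were 0.957 and 0.935, against 0.960 to 0.982 for the other 22. On the first principal component, which held 21.7% of the variance, they lay at -22.3 and -37.4, against -8.60 to 11.6 for the others. The mean difference between 3' and 5' probe sets of Actb and Gapdh, a sign of RNA degradation, was 0.450 and 0.547 on them and 0.360 to 0.605 on the others. Both were kept. Settings without them and, for lists, without single arrays were chosen after seeing the data. Where 1 array is left out, the lone mouse of its group is assumed to vary like the other groups. List medians without 1 array are given where the call was lost or gained or a called median moved by over 1.5 times.

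**Figure D2:**
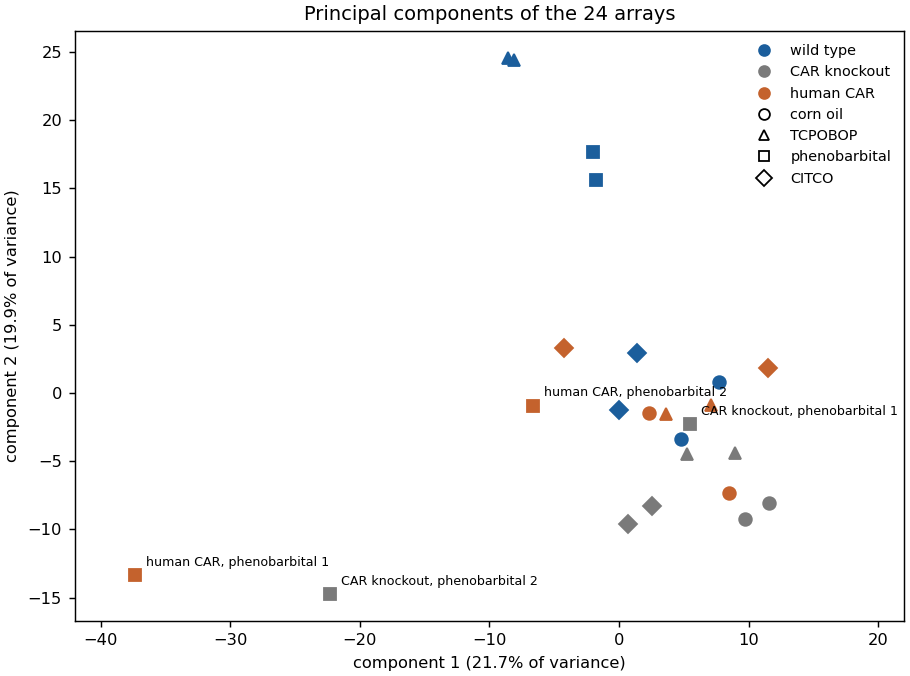
First and second principal components of the 24 arrays, with colour for genotype and marker shape for treatment. The knockout and human CAR phenobarbital arrays that stand apart lie at -22.3 and -37.4 on component 1, and the other 22 between -8.60 and 11.6.

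TCPOBOP in wild-type mice changed 563 genes, 306 higher and 257 lower than corn oil. The largest rise was that of Cyp2b10, a cytochrome P450 used as the standard marker of CAR activity, from 4.94 ± 0.40 to 12.36 ± 0.17 (SD, n = 2 each), a log2 change of 7.42 (SE 0.38, adjusted p = 9.69e-09). Cyp2c55, another P450, rose by 5.51 (SE 0.44, adjusted p = 5.81e-07) and Gstm3, a glutathione transferase, by 4.10 (SE 0.36, adjusted p = 1.51e-06). Further large rises were those of Prom1 (3.88), the estrogen sulfotransferase Sult1e1 (3.33), D17H6S56E-5 (2.92), the chemokine Ccl9 (2.82), Gstt3 (2.79), Gstm2 (2.75), the carboxylesterase Ces2a (2.71), the retinoic acid hydroxylase Cyp26a1 (2.63) and Cnmd (2.53). Gadd45b, a growth arrest and DNA damage gene, rose by 2.31 (SE 0.28, adjusted p = 6.34e-05), the only 1 of 12 early growth genes to pass (4 higher and 1 lower within the list, camera adjusted p = 0.139). Prom1 and Sult1e1 lay below the dim limit on both corn oil arrays, so their fold changes are compressed. Cyp2b10 lay below that limit on 1 corn oil array. Probe sets of Cyp2b10, Gstm3, Ugt2b34, Rdh9 and Cyp7b1 are of a type that can also bind related transcripts, and their signal can hold that of paralogs. Without corn oil replicate 2, the median was 0.45 against 0.20 for early growth genes (gained, adjusted p = 0.0495).

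Of 20 drug-metabolising P450s and their partners, 8 rose and none fell (9 and 1 within the list, camera p = 2.06e-07, and 0.0246 with estimated correlation). They included Cyp2c54 at 1.80, Cyp2c29 at 1.5, Cyp1a2 at 1.15 and Cyp3a11 at 0.87. Of 40 conjugation and other drug-metabolising enzymes, 17 rose and 0 fell (21 and 1 within the list, camera p = 1.71e-13, and 0.0943 with estimated correlation), among them the glucuronosyltransferase Ugt2b34 at 1.44. Among 15 transporters 1 rose, the efflux pump Abcc3 (1.73), and 3 fell (1 and 3 within the list, camera p = 0.416, and 0.773 with estimated correlation). Genes of S phase and mitosis rose together: 20 of 26 were higher and 0 lower (22 and 0 within the list, camera p = 8.98e-29, and 8.48e-06 with estimated correlation). Examples are the mitotic regulator Birc5 at 1.94 (SE 0.12, adjusted p = 4.23e-08), the cyclin Ccnb2 at 1.90, the kinase Cdk1 at 1.83 and the ribonucleotide reductase subunit Rrm2 at 1.81. All 4 lay below the dim limit on both corn oil arrays.

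Fatty acid oxidation genes moved the other way under TCPOBOP in wild type. Of 22 measured, 12 fell and 0 rose (18 and 0 within the list, camera p = 5.87e-14, and 0.0943 with estimated correlation). Ech1 fell by 1.44 (SE 0.26, adjusted p = 0.00249), Eci2 by 0.97, Hadha by 0.81 and Acadvl by 0.66, all enzymes of beta oxidation, and the peroxisomal hydrolase Nudt7 fell by 1.75. The largest fall of all genes was that of the chemokine Cxcl1, which fell by 4.43 (SE 1.14, adjusted p = 0.0279). In knockout mice, looked at after its values were seen, Cxcl1 had a TCPOBOP change of -4.06 (adjusted p = 0.26), and the difference between the genotypes was -0.36 (adjusted p = 0.968). Gstp3 fell by 2.77, Rdh16f2 fell by 2.34, Rdh9 fell by 2.33 and Retsat fell by 2.11, the last 3 being genes of retinoid metabolism. Rdh9 lay below the dim limit on both TCPOBOP arrays. Cyp8b1 and Cyp7b1, enzymes of bile acid synthesis, fell from 10.12 to 7.97 and by 1.94, Ppp1r3c fell by 2.14 and the transporter Slco1a1 fell by 2.09. Of 17 male-biased genes 4 fell (6 within the list, camera p = 0.0255, and 0.525 with estimated correlation). Of 14 female-biased genes 3 rose (3 within the list, camera p = 0.0325, and 0.435 with estimated correlation). Of 13 hepatocyte markers 1 fell (1 within the list, camera p = 0.0185, and 0.11 with estimated correlation). Of 15 bile acid genes 1 rose and 2 fell (2 and 6 within the list, camera p = 0.0489, and 0.525 with estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a change of -0.5 (adjusted p = 0.786) and Pck1, an enzyme of gluconeogenesis, one of -0.37 (adjusted p = 0.803). List medians were -0.41 against -0.45 for male-biased genes (lost, adjusted p = 0.176) and 0.01 against 0.09 for female-biased genes (lost, adjusted p = 0.176) without corn oil replicate 1. List medians were 0.20 against 0.09 for female-biased genes, -0.18 against -0.22 for hepatocyte markers (lost, adjusted p = 0.0973) and -0.30 against -0.33 for bile acid genes (lost, adjusted p = 0.167) without corn oil replicate 2. After TCPOBOP replicate 1 was left out, the median was -0.32 against -0.33 for bile acid genes (lost, adjusted p = 0.156). When TCPOBOP replicate 2 was left out, the medians were -0.29 against -0.45 for male-biased genes (lost, adjusted p = 0.0935), 0.27 against 0.09 for female-biased genes and -0.14 against -0.22 for hepatocyte markers.

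Leaving out any 1 of the 4 arrays compared gave 265 to 315 genes, and 165 of the 563 were called whichever array was left out. Without the 2 arrays that stand apart the count was 884, 48.3% higher, and included all 563. The 8 wild-type arrays alone gave 1065, 44.9% higher, and the stricter dim filter 501, 47.9% higher. Among the named genes, Cyp1a2, Cyp26a1, Cxcl1, Gstp3, Cyp8b1, Slco1a1, Ppp1r3c, Nudt7 and Cyp7b1 each lost the call when at least 1 array was left out. Gstp3 differed between the 2 TCPOBOP mice (6.81 and 10.15), with a change of -1.11 without the TCPOBOP array of replicate 1 and -4.44 without that of replicate 2.

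Phenobarbital in wild-type mice changed 135 genes, 82 higher and 53 lower. With unadjusted p under 0.05, 562 were higher and 682 lower. Cyp2b10 rose by 7.04 (SE 0.38, adjusted p = 2.34e-08) to 11.97 ± 0.13 (SD, n = 2), Cyp2c55 by 4.93 (SE 0.44, adjusted p = 1.13e-05) and Gstm3 by 3.30 (SE 0.36, adjusted p = 7.44e-05). The other large rises were those of Cyp26a1 (2.63), Gstt3 (2.46), Cnmd (2.45), Ces2a (2.19), Gadd45b (2.16), the methyltransferase Inmt (2.11), Gsta2 (2.10), the retinoic acid receptor Rarb (1.99) and the MAP kinase phosphatase Dusp6 (1.88). Of 20 drug-metabolising P450s and partners, 7 rose and 0 fell (13 and 0 within the list, camera p = 6.17e-16, and 0.00157 with estimated correlation), with Cyp2c54 at 1.83, Cyp2c29 at 1.26, Cyp1a2 at 0.98 and Cyp3a11 at 0.83. Of 40 conjugation enzymes, 15 rose and 0 fell (25 and 0 within the list, camera p = 7.06e-24, and 0.0256 with estimated correlation), with Gstm1 at 1.74. Abcc3 rose by 1.66. Of 26 S phase and mitosis genes 2 rose, Cdk1 by 0.70 and Ccnb2 by 0.66 (2 within the list, camera p = 0.00276, and 0.0809 with estimated correlation). Rarb and Cdk1 lay below the dim limit on both corn oil arrays, so their fold changes are compressed. Ccnb2 lay below it on all 4 arrays, so its rise is a difference between values below that limit. Without phenobarbital replicate 2, the median was 0.10 against 0.16 for S phase and mitosis genes (lost, adjusted p = 0.0558).

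Under phenobarbital in wild type, Cxcl1 fell by 5.30 (SE 1.14, adjusted p = 0.0259), the ferritin receptor Scara5 fell by 3.36 and the phosphatidate phosphatase Lpin1 fell by 2.61. A second, dimmer probe set of Scara5 gave 0.26. Cxcl1 and Gnat1 lay below the dim limit on both phenobarbital arrays. The liver transcription factor Foxa3 fell by 1.73, Gnat1 fell by 1.71, the endoplasmic reticulum stress gene Creld2 fell by 1.66, Bhmt, an enzyme of methionine metabolism, fell by 1.20, Map7d1 fell by 1.19 and Rxra, the partner receptor of CAR, fell by 0.86. Several lists with at most 2 passing members had negative medians. The median change was -0.44 for 13 interferon genes (6 lower within the list, camera p = 6.53e-05, and 0.231 with estimated correlation) and -0.23 for 22 acute phase genes (4 lower within the list, camera p = 0.000189, and 0.474 with estimated correlation). Kupffer markers, 12 in all, had a median of -0.48 (0 within the list, camera p = 0.000123, and 0.375 with estimated correlation). The median was -0.46 for 11 gluconeogenesis genes (0 within the list, camera p = 0.00276, and 0.16 with estimated correlation) and -0.20 for 22 fatty acid oxidation genes (0 within the list, camera p = 0.0171, and 0.629 with estimated correlation). Of the 8 genes named in every comparison, Nr1i3, Cyp7a1 and Pck1 did not pass, with changes from -1.10 (Cyp7a1) to 0.48 (Nr1i3), with a smallest adjusted p of 0.273. Leaving out 1 of the 4 arrays gave 19 genes (without the phenobarbital array of replicate 2) to 59, with 19 called in every case, among them Cyp2b10, Cyp2c55, Gstm3, Gstt3, Gstm1, Ces2a, Abcc3, Gadd45b, Rarb, Inmt, Dusp6, Bhmt and Map7d1, while the calls of the other named genes were lost for at least 1 array. The count was 246 without the 2 arrays that stand apart (50.4% higher), 342 with the 8 wild-type arrays alone (45.9% higher) and 410 with array weights (45.9% higher). Leaving out phenobarbital replicate 2 gave a median of -0.14 for fatty acid oxidation genes (lost, adjusted p = 0.154). Without corn oil replicate 1, the medians were -0.24 for interferon genes, -0.43 for acute phase genes, -0.25 for Kupffer markers (lost, adjusted p = 0.0647), -0.72 for gluconeogenesis genes and -0.35 for fatty acid oxidation genes. Leaving out corn oil replicate 2 gave medians of -0.69 for interferon genes, -0.08 for acute phase genes (lost, adjusted p = 0.212), -0.77 for Kupffer markers, -0.31 for gluconeogenesis genes (lost, adjusted p = 0.202) and -0.05 for fatty acid oxidation genes (lost, adjusted p = 0.996).

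CITCO in wild-type mice changed 3 genes. Cyp2b10 rose by 3.23 (SE 0.38, adjusted p = 0.00226) to 8.17 ± 1.14 (SD, n = 2), Gstp3 fell by 4.65 (SE 0.61, adjusted p = 0.00448) and Plekhb2 fell by 0.89 (SE 0.14, adjusted p = 0.0385). Gstp3 also differed between the 2 wild-type TCPOBOP mice (6.81 and 10.15). Plekhb2 lay at 6.34 on wild-type corn oil and at 5.34 to 5.92 in other groups, so a shift of the controls stays open. Of 20 drug-metabolising P450s and partners 1 passed (5 within the list), 18 had positive changes and the median was 0.27 (camera p = 2.78e-06, and 0.0654 with estimated correlation). The 18 cholesterol synthesis genes all had negative changes with a median of -0.65, none passing alone or over the list alone (camera p = 2.91e-05, and 0.984 with estimated correlation). The other 7 genes named in every comparison ran from -0.15 (Cyp7a1) to 1.34 (Cyp2c55), with a smallest adjusted p of 0.401. The Cyp2b10 change was 2.42 without the CITCO array of replicate 2 and 4.04 without that of replicate 1, and it passed in 3 of the 4 cases in which 1 array was left out. Gstp3 passed in 1 of these cases and Plekhb2 in none. The list median was 0.14 for P450s without CITCO replicate 2. Leaving out corn oil replicate 1 gave a median of -0.26 for cholesterol synthesis genes (lost, adjusted p = 0.0529).

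**Figure D3:**
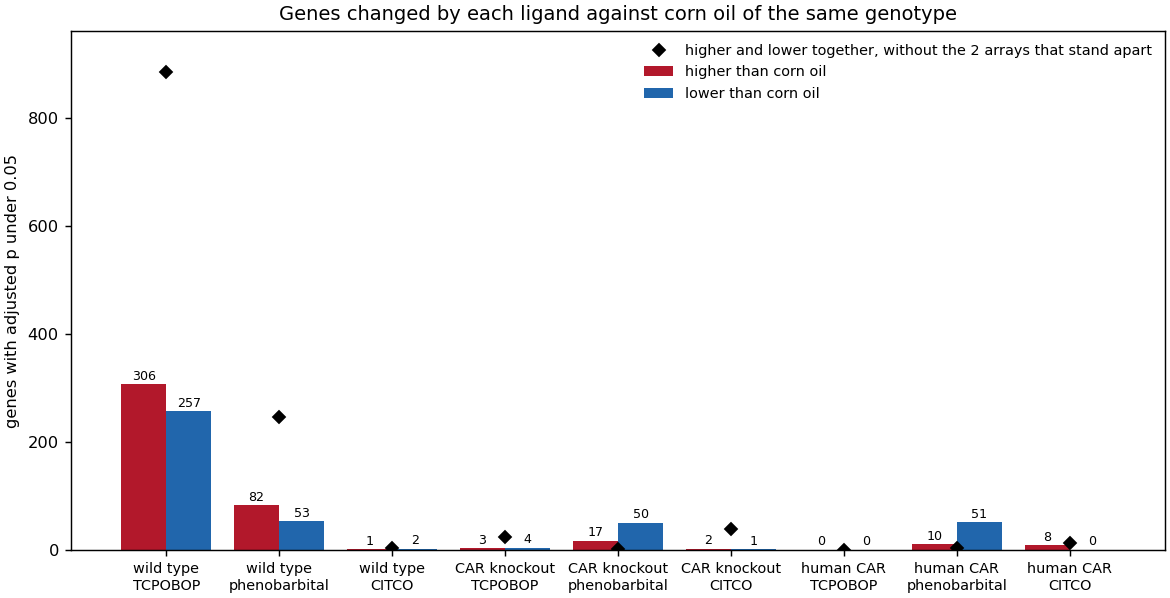
Genes with adjusted p under 0.05 for each ligand against corn oil of the same genotype, higher in red and lower in blue, from all 24 arrays, with diamonds for the total without the 2 arrays that stand apart. Wild-type TCPOBOP gave 306 higher and 257 lower genes, and human CAR TCPOBOP gave 0.

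In knockout mice TCPOBOP changed 7 genes. The male-biased Cyp4a12a, a fatty acid hydroxylase, rose by 3.03 (SE 0.30, adjusted p = 0.000182), the deubiquitinase Usp2 by 1.12 and Cyp2c29 by 1.05. Cyp4a12a lay at 7.58 on knockout corn oil and at 8.74 to 11.07 in the other groups, so a shift of the controls stays open. The macrophage receptor Marco fell by 1.47, the vasopressin receptor Avpr1a fell by 1.32, Slc22a26 fell by 1.06 and the mannose-binding lectin Mbl1 fell by 0.84. Cyp2b10 had a change of -0.29 (adjusted p = 0.791), below the dim limit on both TCPOBOP arrays, and all 8 genes named in every comparison stayed short of the threshold, from -0.54 (Cyp7a1) to 0.60 (Cyp2c55), with a smallest adjusted p of 0.453. Of 12 Kupffer markers 1 fell (8 within the list), and their median change was -0.98 (camera p = 1.59e-11, and 0.33 with estimated correlation). The median was -0.33 for 12 endothelial markers (0 within the list, camera p = 0.000716, and 0.33 with estimated correlation) and -0.32 for 10 stellate cell markers (4 lower within the list, camera p = 0.00599, and 0.33 with estimated correlation). No member passed among 40 conjugation enzymes (7 higher within the list, camera p = 6.33e-05, and 0.33 with estimated correlation) or 26 S phase and mitosis genes (1 lower within the list, camera p = 0.076, and 0.33 with estimated correlation). With 1 array left out, 2 to 4 genes passed, Cyp4a12a and Avpr1a in every case, and without the 2 arrays that stand apart 23 did. Cyp2c29 had a change of 0.66 without the TCPOBOP array of replicate 2. With corn oil replicate 2 left out, the median was -0.09 for stellate cell markers (lost, adjusted p = 0.276). List medians were -0.11 against -0.09 for S phase and mitosis genes (gained, adjusted p = 0.0283) and 0.30 against 0.17 for conjugation enzymes without TCPOBOP replicate 1. Leaving out TCPOBOP replicate 2 gave a median of -0.57 for Kupffer markers.

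Phenobarbital in knockout mice changed 67 genes, 17 higher and 50 lower. At an unadjusted p under 0.05, 1118 were higher and 830 lower. The hepcidin gene Hamp2 rose by 2.09 (SE 0.34, adjusted p = 0.0144), Dnase2a by 1.73, Cyp4a12a by 1.69, Hprt by 1.06 and Abcc3 by 1.05 (SE 0.14, adjusted p = 0.0143). Among the largest falls, Rad51b fell by 2.84 (SE 0.48, adjusted p = 0.016), Tmsb10 fell by 1.71, the cytokine receptor Lifr fell by 1.65 and the macrophage genes Cd5l, Marco, Cd68 and C1qc fell by 1.67, fell by 1.57, fell by 1.46 and fell by 1.4. A second, dimmer probe set of Tmsb10 gave 0.26. Rad51b lay below the dim limit on both phenobarbital arrays. Probe sets of Hamp2, Dnase2a and Tmsb10 can also bind related transcripts. Of 12 Kupffer markers 4 fell (12 within the list, camera p = 7.92e-13, and 0.205 with estimated correlation). The medians of endothelial and stellate cell markers were -0.36 (4 of 12 lower within the list, camera p = 0.00109, and 0.281 with estimated correlation) and -0.44 (4 of 10 lower within the list, camera p = 0.00382, and 0.281 with estimated correlation). Of 13 interferon genes 3 fell (8 within the list, camera p = 1.46e-08, and 0.205 with estimated correlation): Ifi27l2a fell by 1.3, Psmb8 fell by 0.91 and Oas1a fell by 0.69. None of 20 P450s and partners passed (7 higher and 2 lower within the list, camera p = 0.19, and 0.537 with estimated correlation), and the 8 genes named in every comparison ran from -1.76 (Cyp7a1) to 0.51 (Gadd45b), with a smallest adjusted p of 0.232. This comparison holds 1 of the 2 arrays that stand apart, replicate 2 of phenobarbital: without both such arrays 2 genes passed, 1 of them among the 67, and without replicate 2 alone 0 did, while without replicate 1 the count was 933. Leaving out a corn oil array lowered it as far, to 1 without replicate 1 and 0 without replicate 2. No gene was called in every case with 1 array left out, and without the 2 arrays Abcc3 had a change of 1.09 (adjusted p = 0.0656) and Cd5l of -1.12 (adjusted p = 0.146). When phenobarbital replicate 2 was left out, the medians were -0.70 against -1.24 for Kupffer markers, -0.19 for endothelial markers and -0.38 against -0.64 for interferon genes. After corn oil replicate 2 was left out, the median was -0.15 for stellate cell markers (lost, adjusted p = 0.127).

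CITCO in knockout mice changed 3 genes. Hamp2 rose by 2.03 (SE 0.34, adjusted p = 0.0483), Parp16 by 1.37, and the interferon gene Ifi27l2a fell by 1.25 (SE 0.19, adjusted p = 0.0356). Parp16 lay below the dim limit on both corn oil arrays. Chosen after their values were seen, Hprt had a change of 0.96 (adjusted p = 0.0823) and Rad51b one of -2.49 (adjusted p = 0.0823), with values below that limit on both CITCO arrays. For both a difference between sets of mice stays open, as given above. No member of 12 Kupffer markers passed, but all had negative changes with a median of -0.74 (11 lower within the list, camera p = 4.9e-10, and 0.365 with estimated correlation). Of 13 interferon genes 1 fell (4 within the list, camera p = 0.00115, and 0.548 with estimated correlation). Of 20 P450s and partners none passed (0 within the list, camera p = 0.711, and 0.861 with estimated correlation). The 8 genes named in every comparison ran from -0.93 (Cyp7a1) to 0.31 (Pck1), with a smallest adjusted p of 0.698. The 3 knockout comparisons share the 2 corn oil arrays, on which Kupffer markers lay 0.96 higher than on the 6 ligand-treated knockout arrays. With 1 array left out 0 to 6 genes passed and none in every case, and without the 2 arrays that stand apart 39 did, 28.2% of them higher. Without CITCO replicate 1, the median was -0.22 against -0.23 for interferon genes (lost, adjusted p = 0.12). Leaving out CITCO replicate 2 gave a median of -0.36 against -0.23 for interferon genes.

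**Figure D4:**
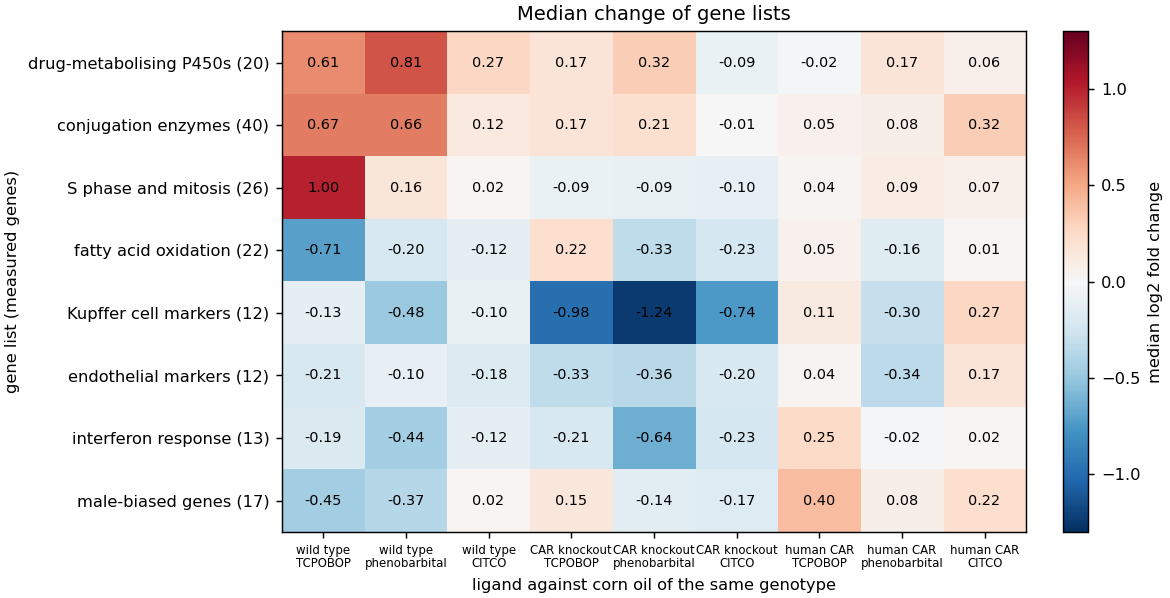
Median log2 fold change of the measured genes of 8 lists in the 9 ligand comparisons, as a colour scale with the value in each cell. S phase and mitosis genes had a median of 1.00 under TCPOBOP in wild type and Kupffer markers one of -1.24 under phenobarbital in knockout mice.

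CITCO in human CAR mice raised 8 genes and lowered 0. Cyp2b10 rose from 8.52 ± 0.43 to 11.53 ± 0.22 (SD, n = 2 each), a change of 3.01 (SE 0.38, adjusted p = 0.0029). Cyp2c55 rose by 2.61 (SE 0.44, adjusted p = 0.0292), Cnmd by 2.41, Cyp2c54 by 1.80, Cyp2c29 by 1.58 (SE 0.19, adjusted p = 0.002), Ces2a by 1.21, 4931406C07Rik by 1.03 and Abcc3 by 0.99. Thus 4 of 20 P450s and partners rose (5 within the list, camera p = 0.000136, and 0.217 with estimated correlation), and 1 of 40 conjugation enzymes did (9 within the list, camera p = 8.4e-06, and 0.595 with estimated correlation). None of 26 S phase and mitosis genes passed, with a median of 0.07 (0 within the list, camera p = 0.0162, and 0.27 with estimated correlation). The other 6 genes named in every comparison ran from -0.57 (Cyp7a1) to 0.71 (Cyp1a2), with a smallest adjusted p of 0.398. With 1 array left out the count was 1 (Cyp2c29, without the corn oil array of replicate 1) to 20, and Cyp2c29 alone passed in every case. Without that corn oil array Cyp2c54 had a change of 1.18. With array weights 0 genes passed, and with the 8 human CAR arrays alone 3 did. None of 12 Kupffer markers passed (0 within the list, median 0.27, camera p = 0.037, and 0.748 with estimated correlation). With CITCO replicate 1 left out, the medians were 0.12 against 0.06 for P450s, 0.17 against 0.32 for conjugation enzymes (lost, adjusted p = 0.128), 0.10 for S phase and mitosis genes (lost, adjusted p = 0.128) and 0.19 for Kupffer markers (lost, adjusted p = 0.447). After CITCO replicate 2 was left out, the medians were 0.12 against 0.06 for P450s and 0.45 for Kupffer markers. List medians were 0.10 for S phase and mitosis genes (lost, adjusted p = 0.211) and 0.49 for Kupffer markers without corn oil replicate 1. After corn oil replicate 2 was left out, the medians were 0.16 against 0.06 for P450s, 0.14 for S phase and mitosis genes and 0.10 for Kupffer markers (lost, adjusted p = 0.978).

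Phenobarbital in human CAR mice changed 61 genes, 10 higher (16.4%) and 51 lower. Cyp2b10 rose by 2.78 (SE 0.38, adjusted p = 0.00807) to 11.30 ± 0.11 (SD, n = 2), Cyp2c54 by 1.71, Gadd45b by 1.61 and Cyp2c29 by 1.48 (SE 0.19, adjusted p = 0.00458). The other rises were those of the interferon-inducible GTPases Ifi47 (1.28) and Irgm1 (0.82), the glutamine synthetase gene Glul (1.17), Jam2 (0.84), Abcc3 (0.72) and Aen (0.56). Among the largest falls, the transcription factors Klf15, Hes6 and Zfpm1 fell by 1.57, fell by 1.56 and fell by 1.4, the potassium channel gene Kcnk5 fell by 1.47, Tpmt fell by 1.46, Etfbkmt fell by 1.45, Bid fell by 1.32 and Ehd3 fell by 1.16, and the monooxygenase Fmo5 fell by 1.04. Kcnk5 lay below the dim limit on both phenobarbital arrays. Probe sets of Hes6 and Fmo5 can also bind related transcripts. Among 20 P450s and partners, 3 rose (5 higher and 1 lower within the list, camera p = 0.00399, and 0.308 with estimated correlation). Of 40 conjugation enzymes 1 fell (2 higher and 2 lower within the list, camera p = 0.509, and 0.87 with estimated correlation). Of 12 early growth genes 1 rose, Gadd45b (7 higher and 1 lower within the list, camera p = 0.00134, and 0.333 with estimated correlation). No member passed of 22 acute phase genes (median 0.28, 0 within the list, camera p = 0.00309, and 0.53 with estimated correlation) or 20 lipogenesis genes (median -0.66, 6 lower within the list, camera p = 0.00357, and 0.473 with estimated correlation). The other 6 genes named in every comparison ran from -2.42 (Cyp7a1) to 1.66 (Cyp2c55), with a smallest adjusted p of 0.0697. Leaving out phenobarbital replicate 1 gave medians of 0.35 against 0.17 for P450s, 0.23 against 0.08 for conjugation enzymes (gained, adjusted p = 0.0171), 0.17 for acute phase genes (lost, adjusted p = 0.366) and 0.23 against 0.74 for early growth genes. After phenobarbital replicate 2 was left out, the medians were 0.15 against 0.17 for P450s (lost, adjusted p = 0.175) and 1.27 against 0.74 for early growth genes. When corn oil replicate 2 was left out, the medians were 0.18 for acute phase genes (lost, adjusted p = 0.107) and 0.73 against 0.74 for early growth genes (lost, adjusted p = 0.052).

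This comparison holds the other array that stands apart, phenobarbital replicate 1 of the human CAR mice. On it the median of 7 neutrophil markers lay 1.5 above their mean over all arrays, and in the comparison 0 of the 7 passed (2 higher within the list, camera p = 0.00399, and 0.473 with estimated correlation). Without both such arrays 4 genes passed, all among the 61: Cyp2b10, Cyp2c29, Gadd45b and Ehd3. Leaving out that replicate alone gave 0 genes and leaving out replicate 2 gave 1311. Without the corn oil arrays of replicates 1 and 2 the counts were 0 and 96, and no gene was called in every case. Without the 2 arrays Klf15 had a change of -0.82 (adjusted p = 0.270) and Glul one of 1.02 (adjusted p = 0.272), and with cyclic loess between arrays 39.6% of 48 genes were higher. With phenobarbital replicate 1 left out, the median was 0.09 against 0.85 for neutrophil markers (lost, adjusted p = 0.804). When phenobarbital replicate 2 was left out, the median was 1.62 against 0.85 for neutrophil markers. The list median was 0.35 against 0.85 for neutrophil markers (lost, adjusted p = 0.052) without corn oil replicate 2.

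TCPOBOP in human CAR mice changed 0 genes in the limma test. At an unadjusted p under 0.05 there were 610 genes, and the smallest adjusted p was 0.411. Cyp2b10 had a change of -1.21 (adjusted p = 0.632), from 8.52 ± 0.43 to 7.31 ± 0.41 (SD, n = 2 each), and Cyp2c55 one of -0.22 (adjusted p = 0.941), and the 8 genes named in every comparison ran from -1.21 (Cyp2b10) to 0.36 (Cyp1a2), with a smallest adjusted p of 0.632. None of 20 P450s and partners (median -0.02, camera p = 0.465, and 0.831 with estimated correlation) or 26 S phase and mitosis genes (median 0.04, camera p = 0.974, and 0.985 with estimated correlation) passed, alone or within the list. Of 17 male-biased genes none passed but all had positive changes, with a median of 0.40 (4 higher within the list, camera p = 2.04e-06, and 0.296 with estimated correlation). Of 17 endoplasmic reticulum stress genes none passed, with a median of -0.28 (1 lower within the list, camera p = 0.000138, and 0.296 with estimated correlation). Without the corn oil array of replicate 2 the count was 11. Without corn oil replicate 1, the medians were -0.02 for P450s (gained, adjusted p = 0.0176) and 0.17 for male-biased genes (lost, adjusted p = 0.0776). Without corn oil replicate 2, the median was 0.91 for male-biased genes. After TCPOBOP replicate 2 was left out, the median was 0.61 for male-biased genes.

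On corn oil, 21 genes differed between knockout and wild type, 8 higher and 13 lower in knockout. Before adjustment, at p under 0.05, 352 were higher and 250 lower. Besides Nr1i3, Gstp3 fell by 4.81 (SE 0.61, adjusted p = 0.00145). Also 4 of 20 P450s and partners were lower (4 higher and 5 lower within the list, camera p = 0.112, and 0.797 with estimated correlation). These were P450s of the 2c family: Cyp2c37 fell by 4.73 (SE 0.89, adjusted p = 0.0346), Cyp2c50 fell by 3.20, Cyp2c29 fell by 3.02 (SE 0.19, adjusted p = 1.52e-07) and Cyp2c54 fell by 2.13. The fatty acid elongase Elovl3 fell by 2.85 and Cyp4a12a fell by 2.76, so that 2 of 17 male-biased genes were lower (6 within the list, camera p = 1.39e-09, and 0.109 with estimated correlation). Ligand-treated knockout groups had Cyp4a12a means of 8.74 to 10.61 against 7.58 on corn oil, so a shift of these controls stays open. None of 14 female-biased genes passed (2 higher within the list, median 0.28, camera p = 0.000223, and 0.109 with estimated correlation). Higher in knockout were Marco (1.73), Rdh16f2 (1.59), BC018473 (1.45), Slc22a26 (1.22) and Avpr1a (0.90). Cyp2c37 in knockout and BC018473 in wild type lay below the dim limit on both arrays. Of 12 Kupffer markers Marco alone passed (1 within the list, camera p = 0.00695, and 0.869 with estimated correlation). No S phase and mitosis gene passed, with a median of 0.17 (7 of 26 higher within the list, camera p = 9.34e-06, and 0.0239 with estimated correlation). Nor did any of the 35 neighbours of Nr1i3 on distal chromosome 1, which a targeted locus can carry along (1 higher within the list, camera p = 0.588, and 0.869 with estimated correlation). The other 7 genes named in every comparison ran from -1.29 (Cyp2c55) to 0.42 (Cyp7a1), with a smallest adjusted p of 0.509. With 1 array left out the count was 4 (without the knockout array of replicate 1) to 15, and Nr1i3, Gstp3, Cyp2c29 and Cyp4a12a passed in every case. Without the 2 arrays that stand apart 31 passed, 51.6% of them higher. Elovl3 had a change of -2.16 and -3.54 without the knockout arrays of replicates 1 and 2. With wild-type replicate 1 left out, the medians were 0.42 against 0.22 for Kupffer markers, -0.08 against 0.08 for P450s (gained, adjusted p = 0.0337) and 0.13 for female-biased genes (lost, adjusted p = 0.0509). With wild-type replicate 2 left out, the medians were -0.79 against -0.49 for male-biased genes and 0.02 against 0.22 for Kupffer markers (lost, adjusted p = 0.55). Without knockout replicate 1, the median was 0.13 against 0.22 for Kupffer markers (lost, adjusted p = 0.0562). When knockout replicate 2 was left out, the medians were -0.96 against -0.49 for male-biased genes and 0.35 against 0.22 for Kupffer markers.

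Human CAR mice differed from knockout mice on corn oil in 11 genes, 4 higher and 7 lower. Cyp2b10 was higher by 3.41 (SE 0.38, adjusted p = 0.00054), Cyp2c29 by 2.73 (SE 0.19, adjusted p = 7.09e-07), Cyp4a12a by 2.12 and Hprt by 1.07. Rad51b fell by 2.76, the macrophage genes Marco and Cd163 fell by 1.34 and fell by 1.23, Ifi27l2a fell by 1.18 and Slc22a26 fell by 1.07. Rad51b lay below the dim limit on both human CAR arrays. The 20 P450s and partners had 2 higher members (4 higher and 1 lower within the list, camera p = 9.81e-05, and 0.0995 with estimated correlation). Of 12 Kupffer markers 1 was lower (9 within the list, camera p = 2.86e-12, and 0.111 with estimated correlation). Of 13 interferon genes 1 was lower (3 within the list, camera p = 1.4e-09, and 0.0995 with estimated correlation). Of 26 S phase and mitosis genes none passed (4 lower within the list, camera p = 1.58e-05, and 0.0319 with estimated correlation). Of the 8 genes named in every comparison the other 7 ran from -0.42 (Cyp1a2) to 0.84 (Cyp2c55), with a smallest adjusted p of 0.809. Cyp2b10 and Cyp2c29 passed whichever of the 4 arrays was left out, the count being 4 (without the knockout array of replicate 1) to 12, and 21 without the 2 arrays that stand apart. Leaving out knockout replicate 1 gave a median of 0.12 against 0.20 for P450s. Leaving out human CAR replicate 2 gave a median of 0.13 against 0.20 for P450s.

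Against wild type on corn oil, 5 genes differed in human CAR mice. Cyp2b10 was higher by 3.58 (SE 0.38, adjusted p = 0.000272), while Nr1i3 was lower as given above, Gstp3 fell by 4.47 (SE 0.61, adjusted p = 0.00496), the secreted protein gene Spp2 fell by 1.31 and Plekhb2 fell by 1.00. No member passed of 18 cholesterol synthesis genes (median -0.51, 0 within the list, camera p = 0.00189, and 0.878 with estimated correlation). Nor did any of 12 Kupffer markers (median -0.41, 0 within the list, camera p = 0.000859, and 0.722 with estimated correlation) or 13 interferon genes (median -0.34, 1 lower within the list, camera p = 0.00017, and 0.722 with estimated correlation). The other 6 genes named in every comparison ran from -0.45 (Cyp2c55) to 0.30 (Cyp3a11), with a smallest adjusted p of 0.677. Cyp2b10 and Nr1i3 passed whichever array was left out, the count being 3 (without the wild-type array of replicate 1) to 22 (without the human CAR array of replicate 2), and 12 without the 2 arrays that stand apart. After wild-type replicate 1 was left out, the medians were -0.21 for cholesterol synthesis genes (lost, adjusted p = 0.273), -0.23 for Kupffer markers (lost, adjusted p = 0.27) and -0.18 for interferon genes. After wild-type replicate 2 was left out, the median was -0.82 for cholesterol synthesis genes. Leaving out human CAR replicate 1 gave a median of -0.25 for cholesterol synthesis genes. With human CAR replicate 2 left out, the median was -0.23 for Kupffer markers (lost, adjusted p = 0.368).

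The effect of TCPOBOP differed between wild type and knockout for 179 genes, 118 with a more positive effect in wild type. The difference of log2 changes was 7.71 (SE 0.54, adjusted p = 5.98e-07) for Cyp2b10, 4.91 (SE 0.62, adjusted p = 0.000231) for Cyp2c55, 3.99 for Prom1, 3.56 for Cyp26a1, 3.47 for Ccl9 and 2.61 for Gadd45b. Of 26 S phase and mitosis genes 14 had a more positive effect in wild type and 0 a more negative one (20 and 0 within the list, camera p = 2.29e-31, and 5.26e-06 with estimated correlation), with the proliferation marker Mki67 at 2.42, Birc5 at 2.10 and Cdk1 at 2.06. Of 22 fatty acid oxidation genes 8 had a more negative effect in wild type (19 within the list, camera p = 2.83e-19, and 0.0479 with estimated correlation), with -1.38 for Cpt1a, -1.79 for Acaa1b and -2.28 for Acot1. Cyp2b10 lay below the dim limit on both knockout TCPOBOP arrays and on 1 corn oil array of each genotype, so its difference rests in part on values below that limit. Prom1, Mki67 and Birc5 lay below it on both arrays of 3 of the 4 groups compared, Acot1 on all 4 wild-type arrays, Cdk1 on both wild-type corn oil arrays and Rdh16 on both wild-type TCPOBOP arrays. The most negative differences were those of Cyp4a12a (-2.56), Retsat (-2.37), Rdh16 (-2.35), Acot1 and Hamp2 (-2.24). Of 20 P450s and partners 2 were more positive in wild type (5 more positive and 1 more negative within the list, camera p = 0.000288, and 0.0895 with estimated correlation). Of 40 conjugation enzymes 10 were more positive and 1 more negative (15 and 2 within the list, camera p = 3.65e-06, and 0.349 with estimated correlation). The other 5 genes named in every comparison ran from -0.72 (Nr1i3) to 1.16 (Cyp1a2), with a smallest adjusted p of 0.0637. Of the 179, 71 were called whichever of the 8 arrays was left out, and all 179 among 324 without the 2 arrays that stand apart, and the calls of Cyp26a1, Cpt1a, Acaa1b, Acot1 and Hamp2 were lost for at least 1 of the 8. Of 12 Kupffer markers 1 was more positive in wild type (1 within the list, median 0.76, camera p = 4.14e-05, and 0.349 with estimated correlation). When wild-type corn oil replicate 2 was left out, the median was 0.49 for Kupffer markers. Without knockout TCPOBOP replicate 1, the median was 1.15 for Kupffer markers. With knockout TCPOBOP replicate 2 left out, the median was 0.47 for Kupffer markers.

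For phenobarbital, 14 genes differed in effect between wild type and knockout. The difference was 6.70 (SE 0.54, adjusted p = 9.8e-06) for Cyp2b10, 4.59 (SE 0.62, adjusted p = 0.00403) for Cyp2c55, 2.35 for Ccl9, 1.92 for the ascorbate transporter Slc23a2 and 1.74 for Rarb, and -1.49 for Bhmt, -1.04 for Dmgdh and -1.01 for Hsd17b10. Rarb lay below the dim limit in 3 of the 4 groups. Of 20 P450s and partners 2 were more positive in wild type (6 within the list, camera p = 4.42e-09, and 0.0104 with estimated correlation). Of 40 conjugation enzymes 1 was (14 within the list, camera p = 2.92e-14, and 0.0907 with estimated correlation). Of 26 S phase and mitosis genes none was (4 within the list, camera p = 3.96e-06, and 0.0104 with estimated correlation). The other 6 genes named in every comparison ran from -0.70 (Pck1) to 1.65 (Gadd45b), with a smallest adjusted p of 0.107. Cyp2b10, Cyp2c55 and Slc23a2 passed whichever of the 8 arrays was left out, and without the 2 arrays that stand apart 15 genes passed, 9 of them among the 14. Of 12 Kupffer markers none passed (2 more positive within the list, median 0.64, camera p = 2.11e-05, and 0.32 with estimated correlation). With knockout phenobarbital replicate 1 left out, the median was 1.15 for Kupffer markers. The list median was 0.22 for Kupffer markers without knockout phenobarbital replicate 2. The list median was 0.36 for Kupffer markers without wild-type corn oil replicate 2.

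Between human CAR mice and knockout, the effect of phenobarbital differed for 1 gene, Hsd17b10 (-1.23, SE 0.16, adjusted p = 0.011), which had an adjusted p of 0.0697 without the 2 arrays that stand apart. None of 12 Kupffer markers passed (3 more positive within the list, median 0.91, camera p = 3.53e-11, and 0.151 with estimated correlation). The difference for Cyp2b10 was 2.44 (adjusted p = 0.197), and the 8 genes named in every comparison ran from -1.72 (Pck1) to 2.44 (Cyp2b10), with a smallest adjusted p of 0.197. The effect of CITCO differed for 3 genes: the difference was 3.49 (SE 0.54, adjusted p = 0.0347) for Cyp2b10, 1.87 for Cd163 and -1.55 for Parp16, which lay below the dim limit in 2 of the 4 groups. Cyp2b10 lay below it on both knockout CITCO arrays and 1 knockout corn oil array. The list of 20 P450s and partners had 1 member more positive in human CAR mice (4 within the list, camera p = 0.000692, and 0.201 with estimated correlation). None of 26 S phase and mitosis genes (3 more positive within the list, camera p = 3.22e-05, and 0.0351 with estimated correlation) or 12 Kupffer markers (9 more positive within the list, camera p = 9.2e-11, and 0.206 with estimated correlation) passed. The other 7 genes named in every comparison ran from -0.55 (Pck1) to 2.35 (Cyp2c55), with a smallest adjusted p of 0.355. Each of the 3 calls was lost when at least 1 of the 8 arrays was left out, the Cyp2b10 call in 7 of the 8 cases, with differences from 3.18 to 3.79. After knockout phenobarbital replicate 1 was left out, the median was 1.43 for Kupffer markers. Without knockout phenobarbital replicate 2, the median was 0.49 for Kupffer markers. When human CAR CITCO replicate 2 was left out, the median was 0.20 against 0.31 for S phase and mitosis genes. With human CAR corn oil replicate 1 left out, the medians were 0.10 against 0.22 for P450s and 0.18 against 0.31 for S phase and mitosis genes.

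Compared with wild type, the effect of phenobarbital in human CAR mice differed for 15 genes, 3 more positive and 12 more negative. The difference was -4.26 (SE 0.54, adjusted p = 0.00464) for Cyp2b10, -3.27 (SE 0.62, adjusted p = 0.0461) for Cyp2c55, -2.97 for Inmt, -2.02 for Rarb, -1.56 for the mitochondrial iron carrier Slc25a37, -1.35 for Gstm1, 1.93 for Glul, 1.23 for Bhmt and 1.08 for Plekhb2. Rarb lay below the dim limit in 3 of the 4 groups. The corn oil level of Cyp2b10 was 8.52 ± 0.43 in human CAR mice against 4.94 ± 0.40 in wild type (SD, n = 2 each). Among 20 P450s and partners, 2 were more negative (6 within the list, camera p = 2.22e-05, and 0.076 with estimated correlation). Of 40 conjugation enzymes 1 was (20 within the list, camera p = 2.53e-17, and 0.076 with estimated correlation). The other 6 genes named in every comparison ran from -1.32 (Cyp7a1) to -0.34 (Nr1i3), with a smallest adjusted p of 0.181. Without the 2 arrays that stand apart 9 genes passed, 6 of them among the 15, Cyp2c55, Glul and Gstm1 not among them, and with 1 array left out the count ran from 0 (without the wild-type corn oil array of replicate 1) to 637 (without the human CAR phenobarbital array of replicate 2).

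The effect of CITCO differed between human CAR mice and wild type for 0 genes in the limma test, with 863 at an unadjusted p under 0.05 and a smallest adjusted p of 0.173. For Cyp2b10 the difference was -0.22 with a 95% interval from -1.37 to 0.93, and the 8 genes named in every comparison ran from -0.41 (Cyp7a1) to 1.27 (Cyp2c55), with a smallest adjusted p of 0.553. The effect of TCPOBOP differed for 171 genes, 59 more positive and 112 more negative in human CAR mice. The difference was -8.63 (SE 0.54, adjusted p = 2.12e-07) for Cyp2b10, -5.73 for Cyp2c55, -3.68 for Prom1, -3.56 for Gstm3, -3.43 for Ccl9 and -2.24 for Gadd45b. It was 3.15 for Cyp7b1, 3.10 for Slco1a1, 2.99 for Cyp8b1, 2.71 for Tsc22d1, 2.45 for Rdh9 and 1.36 for Cpt1a. Of 26 S phase and mitosis genes 13 were more negative (19 within the list, camera p = 3.23e-29, and 7.79e-06 with estimated correlation), with -1.99 for Mki67 and -1.84 for Birc5. Prom1, Mki67 and Birc5 lay below the dim limit on both arrays of 3 of the 4 groups, and Rdh9 on both wild-type TCPOBOP arrays. Of 20 P450s and partners 4 were more negative (1 more positive and 8 more negative within the list, camera p = 1.17e-08, and 0.0133 with estimated correlation). Of 40 conjugation enzymes 12 were (18 within the list, camera p = 8.63e-14, and 0.0796 with estimated correlation). The other 5 genes named in every comparison ran from -0.79 (Cyp1a2) to 0.5 (Nr1i3), with a smallest adjusted p of 0.142. Of the 171, 61 were called whichever of the 8 arrays was left out, and all 171 were among 334 without the 2 arrays that stand apart. When wild-type corn oil replicate 1 was left out, the median was -0.43 against -0.67 for P450s.

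The 8 genes raised by CITCO in human CAR mice were all among the 306 raised by TCPOBOP in wild type, against 0.267 for independent lists of these sizes, in comparisons that share no array. Phenobarbital in wild type and in human CAR mice, which share no array either, had 6 genes in common, 5 higher (0.0895 for independent lists) and 1 lower (0.295). Without the 2 arrays that stand apart, 3 were in common. TCPOBOP and phenobarbital in wild type had 93 genes in common, 65 higher (2.74 for independent lists) and 28 lower (1.49). Their log2 changes correlated at r = 0.710 across genes, which are not independent replicates. These comparisons share their corn oil arrays, and simulated groups without any effect gave r = 0.5 and 0 genes in common. The covariance was 0.0802 against 0.0169 simulated. CITCO and phenobarbital in human CAR mice had 4 genes in common, all higher (0.00873 for independent lists), with r = 0.331 against 0.502 and a covariance of 0.0247 against 0.0169 simulated. With 2 corn oil arrays per genotype the controls could not be split, so part of each excess can come from the shared controls. Under TCPOBOP in knockout and in human CAR mice, in comparisons that share no array with wild type, 48.0% and 60.8% of the 306 genes raised by TCPOBOP in wild type had a positive change, and 65.8% and 57.6% of the 257 lowered ones a negative one.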

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

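The differences between genotypes were tests planned before the data were examined, and the tests on the 2 arrays that stand apart were chosen after the result was seen, except that on RNA degradation. The effect of TCPOBOP differed between wild type and knockout for 179 genes, with differences of 7.71 for Cyp2b10, 4.91 for Cyp2c55 and 2.61 for Gadd45b. That of phenobarbital differed for 14 genes, with 6.70 for Cyp2b10 and 4.59 for Cyp2c55. Between human CAR mice and knockout it differed for 1 gene, and the effect of CITCO for 3, with 3.49 for Cyp2b10. Between human CAR mice and wild type the effect of phenobarbital differed for 15 genes, with -4.26 for Cyp2b10 and -3.27 for Cyp2c55, and that of TCPOBOP for 171, with -8.63 for Cyp2b10, -5.73 for Cyp2c55 and -2.24 for Gadd45b. Cyp2b10 lay below the dim limit on both knockout arrays of TCPOBOP and of CITCO and on 1 corn oil array each of wild type and knockout.

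Of 1239 bright probe sets without a single gene symbol, 69 were higher and 33 lower under TCPOBOP in wild type, 17 higher and 3 lower under phenobarbital in wild type, and 6 lower under phenobarbital in human CAR mice. Their genes were not analysed here.

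The phenobarbital counts in knockout and human CAR mice, 67 and 61, were 2 and 4 without the 2 arrays that stand apart. Degraded RNA was argued against, as 0 of the 2 lay above the other 22 in the difference between 3' and 5' probe sets, and so was a smaller share of hepatocytes, as at least 1 of 5 lists of other cell types lay below the other 22 on each array. More neutrophils in the human CAR mouse stay open, as that list lay above the other 22 arrays by 1.36 (1.5 against at most 0.14), and so do more lymphocytes in the knockout mouse, where the excess was 0.056. Differences of the 2 mice from their group's other mouse correlated at r = 0.449 over 9167 genes, so a shared cause stays open. Tested with 1 mouse against corn oil, whose spread was taken from the other groups, 933 genes were called on the odd knockout mouse and 1311 on the odd human CAR mouse. The other phenobarbital mouse had the same direction in 81.0% and 82.8% of them, a difference of -4.93 and 10.6 percentage points from the highest array of another ligand, with 75.7% to 86.0% on such arrays in knockout, which leaves an effect shared by both mice open.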

How the results depend on the processing

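All settings here were chosen before the data were examined, except leaving out the 2 arrays that stand apart and, in the list tests, single arrays, which were chosen after the result was seen. Where 1 array was left out, the lone sample of its group was assumed to vary like the other groups. With 2 mice per group, 12 groups and 12 residual degrees of freedom, small groups limit precision. Genotype was not separated from litter or date, which are not given. Of 4507 values of named genes under other settings, 3797 kept their call and direction, 598 lost the call, 34 gained one and 78 changed sign, none of them for a gene that passed, and the cause was not tested. Replicate differences of 66 pairs of groups correlated at -0.449 to 0.424 (median 0.035). As 17 lay above 0.1 and 11 below -0.1, shared variation stays open. Counts more than 1.5 times apart from the ones in the report follow.

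At least a 2-fold change besides the threshold left 148 for TCPOBOP in wild type and 117 for its effect in wild type against knockout. For phenobarbital it left 49 in wild type, 24 in knockout and 21 in human CAR mice. The 8 wild-type arrays alone gave 1065 for TCPOBOP, 342 for phenobarbital and 0 for CITCO in wild type. Without the 2 arrays that stand apart there were 884 for TCPOBOP in wild type, 246 for phenobarbital in wild type and 23 for TCPOBOP in knockout. The same setting gave 2 for phenobarbital in knockout, 39 for CITCO in knockout and 4 for phenobarbital in human CAR mice. It also gave 21 for human CAR mice against knockout on corn oil, 12 for human CAR mice against wild type on corn oil and 324 for the TCPOBOP effect in wild type against knockout. Counts there were 5 for the phenobarbital effect in human CAR mice against knockout, 16 for the CITCO effect in human CAR mice against knockout and 9 for the phenobarbital effect in human CAR mice against wild type. In addition it gave 334 for the TCPOBOP effect in human CAR mice against wild type, 3 for genes common to phenobarbital in wild type and phenobarbital in human CAR mice and 164 for genes common to TCPOBOP in wild type and phenobarbital in wild type. The same setting gave 2 for genes common to CITCO in human CAR mice and phenobarbital in human CAR mice. Array weights gave 410 for phenobarbital in wild type. In knockout they gave 207 for TCPOBOP, 14 for phenobarbital and 270 for CITCO, and in human CAR mice 0 for phenobarbital and CITCO. On corn oil they gave 43 for knockout against wild type and 25 for human CAR mice against knockout. The TCPOBOP effect in wild type against knockout gave 409. The phenobarbital effect gave 22 in wild type and 0 in human CAR mice against knockout and 4 in human CAR mice against wild type. The CITCO effect gave 0 in human CAR mice against knockout. The mean of all probe sets of a gene gave 5 for CITCO in wild type, 42 for phenobarbital in knockout and 8 for CITCO in knockout. The same setting gave 12 for knockout against wild type on corn oil and 25 for the phenobarbital effect in human CAR mice against wild type. Cyclic loess between arrays gave 12 for TCPOBOP, 143 for phenobarbital and 9 for CITCO in knockout. It also gave 25 for the phenobarbital effect in wild type against knockout. For human CAR mice against knockout it gave 7 for that effect and 5 for the CITCO effect. The replicate number as a block (replicate block) gave 12 for TCPOBOP in knockout. For human CAR mice on corn oil it gave 17 against knockout and 8 against wild type. It gave 4 and 5 for the phenobarbital and CITCO effects in human CAR mice against knockout. The 8 knockout arrays alone gave 2 for TCPOBOP, 4 for phenobarbital and 8 for CITCO in knockout. With the dim filter at the 60th percentile there were 0 for CITCO in knockout, 108 for phenobarbital in human CAR mice and 0 for the CITCO effect in human CAR mice against knockout. The 8 human CAR arrays alone gave 4 for phenobarbital and 3 for CITCO in human CAR mice. An intensity trend with a robust prior gave 5 for CITCO in human CAR mice. Human CAR mice against knockout on corn oil gave 18 without a dim filter and 24 with the 6 corn oil arrays alone.

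Leaving out 1 of the compared arrays gave 265 to 315 for TCPOBOP in wild type, 19 to 59 for phenobarbital in wild type and 0 to 3 for CITCO in wild type. The counts were 2 to 4 for TCPOBOP in knockout, 0 to 933 for phenobarbital in knockout and 0 to 6 for CITCO in knockout. Ranges were 0 to 11 for TCPOBOP in human CAR mice, 0 to 1311 for phenobarbital in human CAR mice and 1 to 20 for CITCO in human CAR mice. There were 4 to 15 for knockout against wild type on corn oil, 4 to 12 for human CAR mice against knockout on corn oil and 3 to 22 for human CAR mice against wild type on corn oil. The range was 91 to 147 for the TCPOBOP effect in wild type against knockout, 4 to 176 for the phenobarbital effect in wild type against knockout and 0 to 242 for the phenobarbital effect in human CAR mice against knockout. Further ranges were 0 to 12 for the CITCO effect in human CAR mice against knockout, 0 to 637 for the phenobarbital effect in human CAR mice against wild type and 0 to 1 for the CITCO effect in human CAR mice against wild type. Leaving out 1 of the compared arrays gave 84 to 145 for the TCPOBOP effect in human CAR mice against wild type, 1 to 9 for genes common to TCPOBOP in wild type and CITCO in human CAR mice and 0 to 30 for genes common to phenobarbital in wild type and phenobarbital in human CAR mice. The counts were 18 to 70 for genes common to TCPOBOP in wild type and phenobarbital in wild type and 0 to 15 for genes common to CITCO in human CAR mice and phenobarbital in human CAR mice.

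Named genes that did not pass and changed sign were these. With the mean of all probe sets the change was 0.12 for Cyp2b10 (the CITCO effect in human CAR mice minus wild type), -0.044 for Gadd45b (CITCO in wild type), -0.048 for Gadd45b (TCPOBOP in human CAR mice) and -0.011 for Pck1 (the TCPOBOP effect in human CAR mice minus wild type). With 2 arrays fewer the change was 0.005 for Cyp7a1 (phenobarbital in knockout), -0.08 for Gadd45b (phenobarbital in knockout), -0.11 for Nr1i3 (phenobarbital in human CAR mice), -1.10 for Cyp7a1 (the phenobarbital effect in wild type minus knockout), 0.23 for Pck1 (the phenobarbital effect in human CAR mice minus knockout) and 0.78 for Pck1 (the phenobarbital effect in human CAR mice minus wild type). With cyclic loess the change was 0.018 for Cyp1a2 (phenobarbital in human CAR mice). With 1 array left out, changes ran from -0.59 to 0.014 for Cyp2b10, -0.15 to 0.13 for Cyp1a2 and -0.29 to 0.40 for Pck1 (TCPOBOP in knockout) and -1.35 to 0.22 for Cyp7a1 and -0.14 to 0.29 for Nr1i3 (CITCO in human CAR mice). Changes were -0.13 to 0.48 for Cyp2b10, -0.083 to 0.48 for Cyp3a11, -0.55 to 0.13 for Pck1 and -0.027 to 0.17 for Gadd45b (knockout against wild type) and -1.03 to 0.59 for Cyp2b10, -1.20 to 0.37 for Cyp7a1 and -0.38 to 0.023 for Pck1 (the CITCO effect in human CAR mice minus wild type). They were -0.54 to 0.23 for Cyp7a1, -0.25 to 0.12 for Pck1 and -0.039 to 0.16 for Gadd45b (CITCO in wild type) and -3.53 to 0.005 for Cyp7a1, -0.46 to 0.23 for Pck1 and -0.08 to 1.10 for Gadd45b (phenobarbital in knockout). Ranges were -0.038 to 0.30 for Nr1i3, -0.003 to 0.20 for Cyp1a2 and -0.03 to 0.65 for Pck1 (CITCO in knockout) and -0.21 to 0.13 for Nr1i3 and -0.008 to 0.13 for Gadd45b (TCPOBOP in human CAR mice). Changes were -0.11 to 0.39 for Nr1i3 and -0.48 to 0.23 for Cyp1a2 (phenobarbital in human CAR mice) and -0.065 to 0.28 for Nr1i3 and -0.10 to 0.58 for Pck1 (human CAR mice against knockout). They were -0.49 to 0.22 for Cyp1a2, -0.22 to 0.55 for Cyp7a1, -0.17 to 0.23 for Pck1 and -0.18 to 0.022 for Gadd45b (human CAR mice against wild type) and -0.47 to 0.54 for Cyp7a1 and -0.96 to 0.24 for Cxcl1 (the TCPOBOP effect in wild type minus knockout). Ranges were -1.10 to 2.43 for Cyp7a1 (the phenobarbital effect in wild type minus knockout) and -0.30 to 0.20 for Nr1i3, -0.002 to 0.32 for Cyp3a11, -0.13 to 0.58 for Cyp1a2, -2.42 to 1.11 for Cyp7a1 and -3.51 to 0.073 for Pck1 (the phenobarbital effect in human CAR mice minus knockout). Changes were -0.27 to 0.16 for Nr1i3 and -0.42 to 1.15 for Cyp7a1 (the CITCO effect in human CAR mice minus knockout) and -2.80 to 0.78 for Pck1 (the phenobarbital effect in human CAR mice minus wild type). They were -0.68 to 0.092 for Cyp7a1 and -0.094 to 0.33 for Pck1 (the TCPOBOP effect in human CAR mice minus wild type).

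Of 68 called lists in the report, 55 lost the call with the estimated correlation. With at least 1 array left out 25 lost it, and the median of 41 moved by over 1.5 times. Lists that had not passed and changed direction in the camera test (not always that of the median) with 1 array left out had adjusted p-values of 0.0171 to 0.696 for conjugation enzymes (phenobarbital in human CAR mice), 0.407 to 0.995 for P450s and partners (CITCO in knockout) and 0.352 to 0.857 for S phase and mitosis genes (TCPOBOP in human CAR mice).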

Other observations

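All tests in this part were chosen after the result was seen, except that on the neighbours of Gstp3. Kupffer cell markers were higher by 0.96 on the 2 corn oil knockout arrays than on the 6 ligand-treated knockout arrays, endothelial markers by 0.31 and stellate cell markers by 0.29, while lymphocyte markers differed by -0.16 (interval -0.31 to -0.01) and neutrophil markers by -0.10 (interval -0.67 to 0.47). The Kupffer and endothelial lists moved apart by 0.65 (95% interval 0.299 to 1.01 from the spread between mice within groups, with a lower end of 0.043 or more with any 1 of the 8 arrays left out, and exact permutation p = 0.0714 over 28 splits). This argues against a smaller share of hepatocytes, which raises other cell types alike, as the whole cause, and a change in Kupffer cells stays open. Loss of CAR alone was not separable: ligand-treated knockout arrays minus ligand-treated wild-type arrays gave -0.42 (exact permutation p = 0.0801 over 924 splits).

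Gstp3, a glutathione transferase, lay between 6.13 and 7.07 on the 16 arrays without mouse CAR. Of the 8 wild-type arrays 3 lay within that range and the others between 10.15 and 11.67, which argues against absence of mouse CAR as the whole cause. Of the 20 nearest tested genes, by the GRCm38.p6 gene table, 1 (Ndufs8) correlated with Gstp3 above the 99th percentile of all genes. A segment that shifts few neighbours stays open, as does what else differed between the wild-type mice.

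The labels give all mice as female. Of 3 Xist probe sets 0 lay above the dim limit on all 24 arrays and 2 lay above it on none, and of 13 probe sets of genes on the Y chromosome 2 lay above it on all arrays and 9 on none. These 2, and the 1 Xist probe set above it on 20 arrays, are of a type that can bind related transcripts, and the other probe sets of the same genes lay above it on none. Of 17 male-biased liver genes 15 lay above it on all arrays, and of 18 female-biased genes 5 did.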
